A study of Mus musculus with 2 samples.

How the data were processed

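Kidney RNA labelled Glis2 mutant and kidney RNA labelled wild type were compared on 2 two-colour Agilent mouse arrays. Per the labels, 500 ng of total RNA was amplified and labelled with Cy3 or Cy5, 750 ng of each labelled cRNA was hybridised for 17 hours, and the arrays were scanned and read with Agilent Feature Extraction, whose version is 8.1.1.1 per the file headers. Per the file headers, the scanner software wrote the mean and local background intensity of each spot in both channels, before any normalization. Per the file headers, its log10 ratio of Cy5 over Cy3 came after its own background subtraction, spatial detrending and linear and lowess dye normalization. The p-value of each log ratio was also written by the scanner software, per the file headers, from its own error model within the array. The authors' deposited value table for the series holds log10 ratios, which equalled the scanner's log ratio with the sign turned on all 22393 features of each array, with a largest difference of 0 and a column median of 0 on both arrays. Its scale, centring and direction (Cy3 over Cy5) are therefore known.

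Each array held 21318 spots that were not controls, for 20868 distinct probes, and 1075 control spots. Between 94.6% and 97.4% of spots were well above background per channel by the scanner software's flag, and 7 to 17 spots per channel were saturated. Negative control spots were brighter on replicate 2, with a mean net signal of 68.9 (SD 58.2) in Cy3 and 21.6 (SD 20.5) in Cy5. On replicate 1 they had 13.1 (SD 4.85) and 3.54 (SD 1.66). A stricter floor set from these controls was passed by 16534 spots. Each array was its own slide and scan day and held both genotypes, so a slide effect common to both channels cancels in the ratio. Slide, scan day and dye orientation cannot be told apart, and the values per array are the values within each slide. Probes were named through the accession in the array design (14302 spots), then the current symbol (2439) or an unambiguous older symbol (2300), using a table of mouse genes for the assembly GRCm38.p6; 2277 spots kept the name in the file. The array files name no genome build, so no coordinates are given.

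R 4.3.3 and limma 3.58.1 were used. Mean signals were corrected with normexp (offset 50) against the median local background, and log ratios were normalized by loess within each array, with control spots given no weight. The ratio of replicate 1 was turned so that both arrays read mutant over wild type. Control spots and 88 spots with an outlier flag were left out. Spots had to be well above background in the mutant channel of both arrays or in the wild type channel of both, which 20107 spots met. Spots of a probe were averaged, and the probe with the highest mean intensity stood for its gene. Of 51 called genes with over 1 probe, 16 had probes that differed in direction. limma's lmFit and eBayes tested the mean log2 ratio of 18357 genes against 0, with 1 residual degree of freedom and 6.58 prior degrees of freedom, and Benjamini-Hochberg adjustment. Each SE is limma's moderated SE, which draws a gene's spread towards that of all genes, so it can lie above or below the SE of its 2 values alone. A gene was called at an adjusted p under 0.05. As the offset adds to both channels, log2 ratios understate the change, and most so for dim spots.

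The 32 gene lists, the tests of the main comparison and of the lists, and the rule for named genes were fixed before the data were examined; the tests of explanations in the closing section were not, and those of neighbouring genes and attached fat were chosen after the results were seen. The rule takes Glis2, the 12 called genes with the largest mean log2 ratio in each direction among those with the same direction on both arrays, and up to 4 called members of each list with the largest absolute mean; where a list is described, its 4 members of largest absolute mean may be given as values. Some genes that the rule takes are not reported here. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 32 lists. Camera was also run with the correlation estimated from the 2 arrays. That test has 1 residual degree of freedom and little power, so a high adjusted p from it does not count against a list. The steps were tested on simulated data made from the measured intensities of 18357 genes. For mutant over wild type, 31.3% of genes changed by 1.5-fold, 91% of those changed by 2-fold and 100% of those changed by 4-fold were called in the right direction. In the simulation 6.33% of calls were unchanged genes. Its noise was drawn independently for each spot and array from the spread that limma fitted, without dye effects of single genes. The 6.33% is therefore not an error rate of the real calls. Simulated changes of 2-fold and 4-fold had median fitted absolute log2 ratios of 0.812 and 1.67.

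Alternatives covered the background correction, its offset, the normalization within and between arrays, the scanner's own ratios, the filter on dim probes, the choice of probe, the variance model, the thresholds, each array alone, the arrays as 1 replicate, and other tests of the lists. A stricter floor from the 162 negative control spots, and a count without the 100 tested genes nearest to Glis2, were added after seeing the data.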

Results

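Gene expression in whole mouse kidney was measured on 2 two-colour Agilent oligonucleotide arrays. Each held RNA labelled Glis2 mutant in one dye and RNA labelled wild type in the other. The array titles name these Glis2 KO and Glis2 WT. Glis2 encodes a Krüppel-like zinc finger transcription factor that is mutated in a form of nephronophthisis, an inherited fibrotic and cystic kidney disease. The arrays formed a dye-swapped pair: the mutant RNA carried Cy3 in replicate 1 and Cy5 in replicate 2. Per the series description, RNA of 3 kidneys was pooled, mice of postnatal day 25 and 60 were studied, the RNA came from 2 independent experiments, and each array analysis was run in duplicate. The labels do not state the age behind either array, or whether these arrays are the 2 experiments or duplicates of the same RNA pools. The spread between the 2 arrays may therefore be technical, and whether any p-value covers the spread between mice is not known. limma's p-values per gene rest on the spread between these 2 arrays, drawn towards that of all genes. Camera's p-values with the preset correlation compare a list's genes with all other genes, taken as nearly independent. Their small size therefore does not come from replication. Median spot signal over local background lay between 4.06 and 5.18 in the 4 channels, and the number of arrays limits the precision. After filtering, 18357 genes were compared, and their log2 ratios (mutant over wild type) correlated across genes with a Pearson r of 0.587 between the arrays, although genes are not independent replicates.

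The first question was the level of Glis2 itself. The Glis2 probe gave log2 ratios of 0.32 and 0.16 on the 2 arrays, with a mean of 0.24 ± 0.11 (moderated SE, n = 2) and an adjusted p of 0.328 in limma, whose moderated SE borrows the spread of all genes (the SD between the arrays was 0.11). Its level was therefore not lower in the RNA labelled mutant. The sources used here do not say which part of the gene was altered or whether the probe lies in it, so this probe does not check the labels, and every direction below refers to the RNA labelled mutant.

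The main comparison asked which transcripts differed between mutant and wild type kidneys. The largest rises in the RNA labelled mutant were in Cfd, the complement factor D that adipocytes secrete (log2 ratio 3.17 ± 0.12, moderated SE, n = 2, or 9.0-fold), and Mgp, a matrix protein that inhibits calcification (2.88 ± 0.11). They were followed by Lyz2, a lysozyme of macrophages (2.5), the MHC class II gene H2-Ab1 (2.48), Car3, a carbonic anhydrase abundant in fat and muscle (2.33), and the adipocyte hormone gene Adipoq (2.23). The 12 largest rises also held H2-Aa, Cd74, Cidec, C3, H2-Eb1 and the lysosomal protease gene Ctss, at log2 ratios between 2.06 and 2.22. The largest falls were in Bfar, a regulator of apoptosis (-2.41 ± 0.11, or 5.30-fold lower), and Hdc, which encodes the histamine-forming histidine decarboxylase (-2.18 ± 0.12). Slc49a4 (-1.93), the growth factor gene Igf2 (-1.93), the steroid-metabolising Akr1c18 (-1.90) and Ywhaz (-1.74) came next, and then Cyp4b1 (-1.50), Pik3c2g, Azgp1, Ugt2b38, Gldc and Mpst, the last at -1.16. Slc49a4 differed most between arrays among these falls, at -2.51 and -1.34. A second Bfar probe gave a mean of 0.07, so the fall holds for 1 of its 2 probes. Over the alternative ways of processing, the Bfar log2 ratio ran from -3.51 to -1.17.

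In total limma called 919 genes at an adjusted p under 0.05, of which 696 were higher and 223 lower in the RNA labelled mutant. By size alone, 134 genes were at least 2-fold higher and 13 at least 2-fold lower on both arrays, while 0 genes passed that size in opposite directions. The limma count did not hold with the scanner software's own log ratios: limma then called 0 genes, with 2522 at an unadjusted p under 0.05, against 3018 in the main setting. With those ratios 225 genes were at least 2-fold higher and 36 at least 2-fold lower on both arrays, and 17 passed that size in opposite directions.

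**Figure D1:**
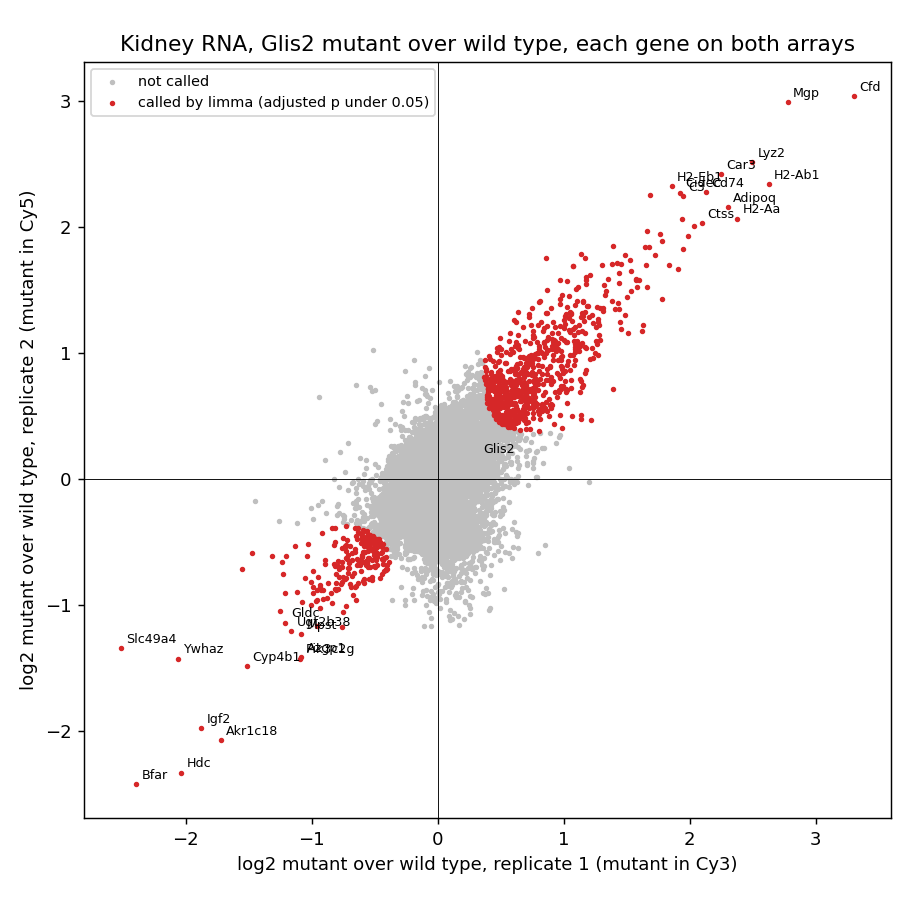
Each point is 1 of 18357 genes, with its log2 ratio of mutant over wild type on replicate 1 (horizontal axis) and replicate 2 (vertical axis); red points are the 919 genes called by limma, and the names mark Glis2 and the 12 largest rises and falls. Cfd lies at 3.30 and 3.04 and Bfar at -2.39 and -2.42, while Glis2 lies near the centre.

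Of 41 measured genes of the extracellular matrix and of myofibroblasts, 26 rose, 0 fell and 15 were not called (32 higher when adjusted over the list alone), with a median log2 ratio of 0.81. Mgp led the list, followed by the fibrillar collagen genes Col3a1 (1.97 ± 0.15, moderated SE, n = 2) and Col1a2 (1.96 ± 0.11) and the collagen-binding Sparc (1.75 ± 0.11). The list was higher in limma's camera test with a preset correlation (adjusted p = 5.8e-28). With an estimated correlation the adjusted p was 0.335. Here and below, that second test has 1 residual degree of freedom and could hardly call any list. Among matrix-remodelling proteases and inhibitors, 5 of 22 members were called higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.21 (0.18 and 0.34 on the 2 arrays). The membrane-bound collagenase gene Mmp14 reached 1.82, the procollagen protease gene Adamts2 1.54 and Ctsk 1.24, and camera gave an adjusted p of 7.83e-07 with the preset and an adjusted p of 0.335 with an estimated correlation.

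Of 28 markers of macrophages and dendritic cells, 17 were called higher and 0 lower (22 and 0 adjusted over the list alone), with a median of 0.80, and the examples were Lyz2, the complement component gene C1qa (1.86 ± 0.11, moderated SE, n = 2), the adaptor gene Tyrobp (1.63 ± 0.11) and Aif1 (1.59 ± 0.11). Among chemokines, cytokines and leukocyte adhesion molecules, 15 of 40 were called higher and 0 lower (21 and 0 adjusted over the list alone). The median was 0.39, with a range from 0.245 to 0.59 over the alternatives. Cxcl14 (2.0), the adhesion molecule Vcam1 (1.79), the interferon-induced chemokine Cxcl10 (1.59) and Cx3cl1 (1.33) led that list. Camera gave adjusted p = 2.31e-20 for the macrophage list and 5.22e-12 for the chemokine list with the preset correlation, and adjusted p = 0.335 for both with an estimated correlation.

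Of 23 markers of T and natural killer cells, 2 were called higher, Cd52 (1.83 ± 0.11, moderated SE, n = 2) and the killer cell receptor gene Klrd1 (0.62 ± 0.13), and 7 when adjusted over the list alone; 0 were lower. Cd52 is also carried by other leukocytes. The list median was 0.20, with an adjusted p of 9.34e-05 in camera and an adjusted p of 0.363 with an estimated correlation. Among 14 markers of B and plasma cells, Cd79b (0.66) and Cd72 (0.65) were called higher (2 adjusted over the list alone), with a list median of 0.07 and a camera adjusted p of 0.311. Of 8 neutrophil markers 0 were higher and 1, Chil3, was lower (-0.49), as also over the list alone; the list median was 0.03, its camera direction was down, and its adjusted p was 0.859.

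Antigen presentation genes had a median of 1.17. Of the 17 members 14 were called higher and 0 lower (16 and 0 adjusted over the list alone), led by H2-Ab1, H2-Aa, Cd74 and H2-Eb1, which form and load MHC class II. Of 19 complement genes 11 were called higher and 0 lower (12 higher and 1 lower over the list alone), with a median of 0.80, among them C3 (2.1 ± 0.12, moderated SE, n = 2) and C1qa (1.86). Cfd and the C1q genes also stand on the adipocyte and macrophage lists. Among 34 interferon response genes, 13 were called higher and 0 lower (23 higher and 1 lower over the list alone), with a median of 0.39, led by Ifi27l2a (1.77), Ifitm3 (1.18), Ifi205 (1.08) and Isg15 (1.08). The camera adjusted p was 1.15e-22, 8.06e-12 and 7.35e-14 for these 3 lists, and adjusted p = 0.335 for each with an estimated correlation.

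Of 30 tubular injury genes, 14 were called higher and 1 lower (19 and 1 adjusted over the list alone), with a median of 0.50. The calcium-binding S100a6 (1.47 ± 0.11, moderated SE, n = 2), the injury marker Lcn2 (1.46 ± 0.15), and Anxa1 (1.25) and Anxa2 (1.09) led the list. The lower member was Egf, which is also a distal tubule gene. The other 15 members were not called. Among these was the injury marker Havcr1 (-0.07, adjusted p = 0.809 in limma), named after its value was seen. The list therefore did not rise as a whole. Camera gave adjusted p = 5.22e-12, and adjusted p = 0.335 with an estimated correlation. Of 13 acute phase genes, 3 were called higher and 0 lower (5 and 0 adjusted over the list alone): Hp (1.23), Socs3 (1.16) and Cp (0.98). Their list median was 0.18, with adjusted p = 0.00237 in camera and adjusted p = 0.335 with an estimated correlation.

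Of 67 proximal tubule genes, 15 fell, 0 rose and 52 were not called (35 lower when adjusted over the list alone), and the median was -0.31. The amino acid transporter gene Slc7a13 (-0.91 ± 0.11, moderated SE, n = 2), the acyl-CoA synthetases Acsm3 (-0.86 ± 0.12) and Acsm1 (-0.70 ± 0.11), and Keg1 (-0.67 ± 0.12) fell most among the called members. Camera gave adjusted p = 5.45e-18, and adjusted p = 0.335 with an estimated correlation. Fatty acid oxidation genes went both ways among the called members, with Cyp4a14 (-0.72) and Ehhadh (-0.58) lower and the regulators Pdk4 (0.93) and Ppargc1a (0.69) higher. That list of 28 had 2 higher and 2 lower calls (2 higher and 5 lower over the list alone), a median of -0.18, and adjusted p = 0.000572 in camera and adjusted p = 0.335 with an estimated correlation.

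Of 26 genes on the loop of Henle and distal tubule list 4 were called lower and 0 higher (the same over the list alone). Among them were Egf (-0.96 ± 0.11, moderated SE, n = 2) and Kl (-0.52). The list as fixed also holds the renin gene Ren1 (-0.60, called lower), although renin is made by juxtaglomerular cells and not by these tubules. The list median was -0.02, with adjusted p = 0.0411 in camera, adjusted p = 0.363 with an estimated correlation, and a range from 0.0323 to 0.539 over the alternatives. Against 10000 random lists matched on intensity, this median lay at percentile 26.93, so that comparison showed no shift of the list. Of 28 collecting duct genes, Atp6v1b1 (0.71) and Fxyd4 (0.68) were called higher and Aqp4 (-0.53) lower (7 higher and 3 lower over the list alone), with a median of 0.08 (0.06 and 0.18 on the 2 arrays) and a camera adjusted p of 0.113. Of 30 podocyte and glomerulus genes, Tcf21 (1.08), which marks podocytes and stroma, was higher and Vegfa (-0.53) lower (5 and 2 over the list alone), with a median of 0.13 (0.09 and 0.23 on the 2 arrays), adjusted p = 0.0263 in camera and adjusted p = 0.507 with an estimated correlation. Of 24 endothelial genes, Ramp2 (0.71) and Cd34 (0.64) were called higher and 0 lower (3 and 0 over the list alone), with a median of 0.26 (0.15 and 0.27 on the 2 arrays), adjusted p = 0.000572 in camera and adjusted p = 0.363 with an estimated correlation.

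**Figure D2:**
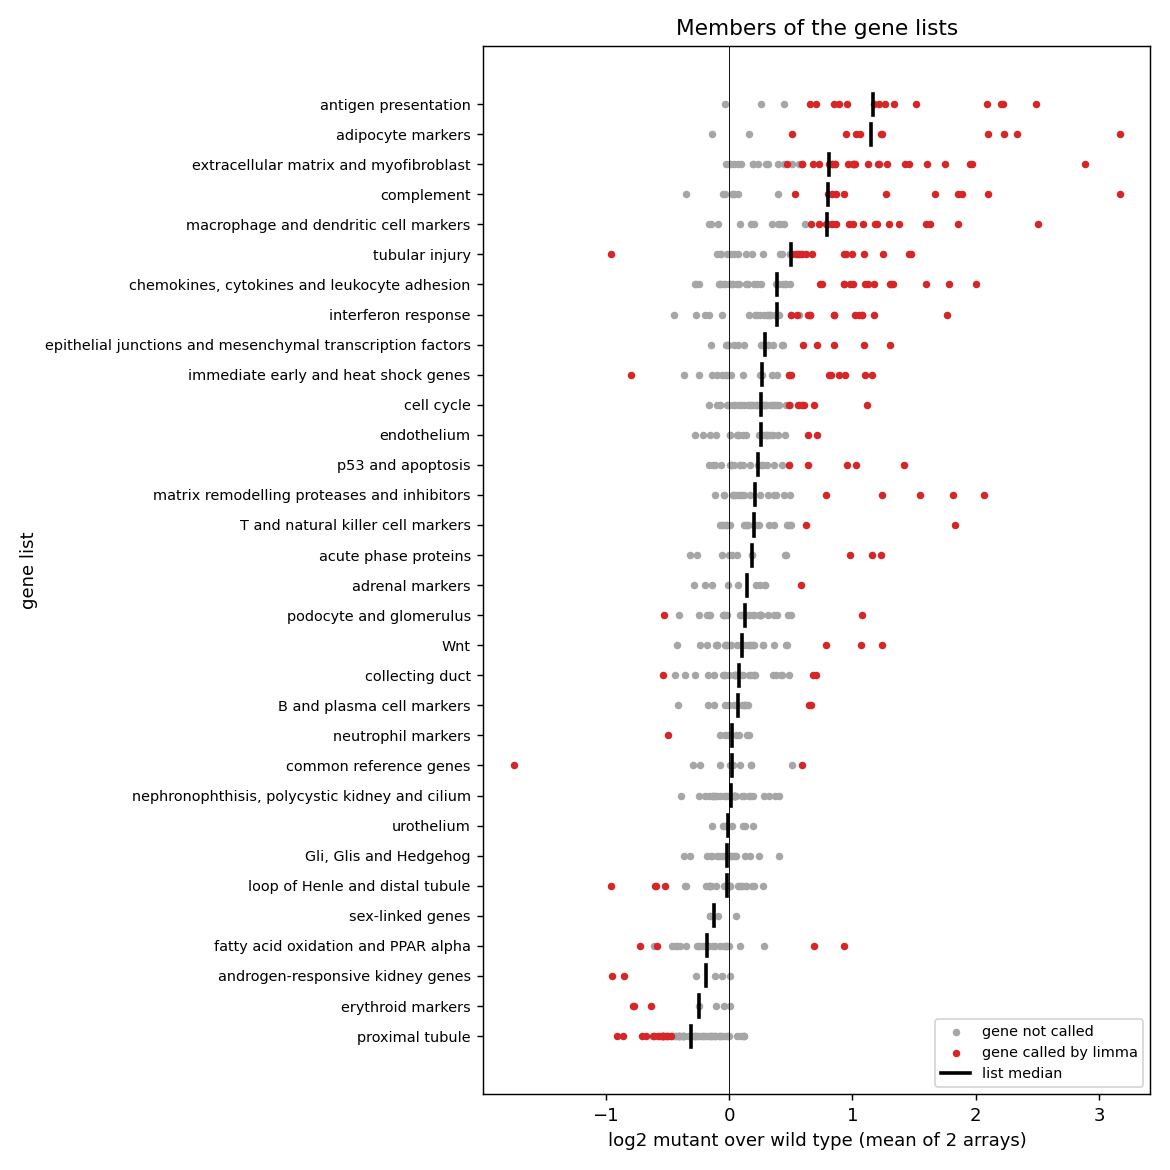
Each row is 1 of the 32 gene lists, ordered by median, and each point is a member's mean log2 ratio of mutant over wild type over 2 arrays (horizontal axis); red points are genes called by limma and the black bar is the list median. Antigen presentation (median 1.17 over both arrays) and adipocyte markers (1.15) stand at the top and the proximal tubule (-0.31) at the bottom.

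Markers of fat moved with the immune and matrix genes. Of 12 adipocyte markers 10 were called higher and 0 lower, as also over the list alone, with medians of 1.19 and 1.22 on the 2 arrays. Cfd, Car3, Adipoq and the lipid droplet gene Cidec (2.1 ± 0.12, moderated SE, n = 2) led this list, whose adjusted p was 1.98e-16 in camera and whose adjusted p was 0.335 with an estimated correlation. Among 10 adrenal markers 1 was called higher, Hsd3b1 (0.58, with 0.38 and 0.78 on the 2 arrays), as also over the list alone, with a list median of 0.15 (0.02 and 0.25 on the 2 arrays) and a camera adjusted p of 0.296. Hsd3b1 was dim, with a mean log2 intensity of 6.60, and dropped out when both channels had to be well above background. Of 9 urothelial markers 0 were called, and the list median was -0.01, with a camera direction of up and an adjusted p of 0.938. Of 7 erythroid markers 3 were called lower and 0 higher, as also over the list alone: Hbb-b2 (-0.78), Hba-a1 (-0.77) and the heme synthesis gene Alas2 (-0.63). Their list median was -0.24, with a range from -0.535 to -0.197 over the alternatives. It had adjusted p = 0.000572 in camera and adjusted p = 0.335 with an estimated correlation.

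Of 33 nephronophthisis, polycystic kidney and cilium genes 0 were called, over all genes or over the list alone. The list median was 0.02, which turned to -0.01 with median centring, and camera gave an adjusted p of 0.859. Of 18 Gli, Glis and Hedgehog genes 0 were called on either count, with a median of -0.02 and a camera adjusted p of 0.627; Gas1, with the largest absolute value, had a log2 ratio of 0.41 and an adjusted p of 0.144. Of 29 Wnt genes 3 were called higher and 0 lower (5 higher and 1 lower over the list alone): Dkk3 (1.24 ± 0.11, moderated SE, n = 2), Nkd1 (1.07) and Ccn4 (0.78). Their median was 0.10 (0.06 and 0.09 on the 2 arrays), with adjusted p = 0.0189 in camera and adjusted p = 0.363 with an estimated correlation. Of 20 epithelial junction genes and mesenchymal transcription factors, 5 were called higher and 0 lower (8 and 0 over the list alone), with a median of 0.29. Cdh11 (1.31, with 0.86 and 1.75 on the 2 arrays) and S100a4 (1.1), both genes of mesenchymal cells, were among them. The other calls were Prrx1 (0.85, with a second probe at -0.10), Zeb2 (0.71) and Snai2 (0.60), so no epithelial junction gene was called. Camera gave this list adjusted p = 9.07e-06, and adjusted p = 0.335 with an estimated correlation. As the list pools both kinds of genes, its median and camera test do not show how each kind moved.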

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

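The stricter floor and the count without genes near Glis2 were chosen after seeing the data, and neither moved a count by over 1.5 times. Of the 99 genes of the naming rule 0 changed sign under any alternative. Apart from Glis2, the rule takes only called genes with the same direction on both arrays. Their kept sign therefore follows largely from that choice and is no separate evidence. Calls depended on the processing: against 696 higher and 223 lower, limma called 302 and 56 with offset 16, 235 and 48 with median centring (35 and 31 named genes losing their call with median centring and offset 16), and 1540 and 932 (62.3% higher, against 75.7%) with a trended, robust prior. With the scanner's log ratio, and with the series value table, which holds the same ratios, limma called 0 and 0 (2522 at an unadjusted p under 0.05), 98 named genes lost their call, and the size counts became 225 and 36, with 17 in opposite directions. With a 1.5-fold minimum 135 lower calls were left, and the scanner's own P under 0.01 on both arrays gave 460 higher. Size counts were 405 and 97 at 1.5-fold and 26 and 4 at 3-fold, as the threshold sets them. For 1 array alone the genes 2-fold higher numbered between 167 and 212 and those lower between 32 and 35, since 1 array need pass; limma's count had no value there or with the arrays averaged. The causes of the other shifts were not tested. Glis2 stayed between 0.14 and 0.32, with adjusted p from 0.26 to 0.727. With an estimated correlation in camera 0 of the 23 list calls were kept. Medians of 0.81 (matrix), 0.39 (chemokines), 0.80 (macrophages) and -0.31 (proximal tubule) had adjusted p = 0.335, and 0.20 (T and natural killer cells) had adjusted p = 0.363. The lowest unadjusted p of that test was 0.0584, for antigen presentation. With 1 residual degree of freedom it has little power, so this loss does not decide whether the lists shifted. The T cell median was 0.233 to 0.238 on single arrays. Without 1 replicate in turn, 13 and 11 of the 32 list medians counted as moved, and 2 changed sign each time. Not all of those that moved did so by more than the gap between the 2 arrays' medians. By over 1.5 times moved those of endothelium (0.153 to 0.265), podocytes (0.0896 to 0.232), collecting duct (0.0557 to 0.178), Wnt (0.0603 to 0.0923), matrix proteases (0.181 to 0.343), adrenal (0.0223 to 0.246), neutrophil (0.0141 to 0.073), loop of Henle (-0.0259 to -0.0082) and reference genes (0.0166 to 0.088), and of the called named genes Ccnb2, Cdh11 and Hsd3b1. Medians that changed sign were those of cilium genes (-0.0119 with median centring; -0.00974 to 0.0677 on single arrays), reference genes (-0.0236 with median centring), sex-linked genes (-0.257 to 0.0407 on single arrays), urothelium (-0.0323 to 0.167) and Hedgehog genes (-0.0325 to 0.0202). Signal over background, 4.06 to 5.18, limits dim genes.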

Other observations

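The tests of neighbouring genes and of attached fat were chosen only after the results were seen. Beyond the groups of the report, 6 of 40 cell cycle genes were called higher, 0 lower and 34 were not called (12 and 0 adjusted over the list alone), among them Cdca3 (1.12 ± 0.11, moderated SE, n = 2), Ccnb2 (0.69, with 0.44 and 0.93 on the 2 arrays), Stmn1 (0.61) and Pcna (0.59). Their median was 0.26, with adjusted p = 2.98e-08 in camera and adjusted p = 0.335 with an estimated correlation. Of 25 p53 and apoptosis genes 5 were called higher and 0 lower (7 and 0 over the list alone), among them the inflammatory caspase gene Casp4 (1.42), the p53 target Phlda3 (1.03) and Bbc3 (0.95). Their median was 0.24, with adjusted p = 2.37e-05 in camera and adjusted p = 0.335 with an estimated correlation. Of 23 immediate early and heat shock genes, 8 were called higher and 1 lower (11 and 2 over the list alone), with Socs3 (1.16), Junb (1.1) and Egr2 (0.94) at the top. Their median was 0.27, with adjusted p = 0.000343 in camera and adjusted p = 0.335 with an estimated correlation. Of 12 common reference genes, Actb was higher (0.59) and Ywhaz lower (-1.74), with 2 higher and 1 lower over the list alone, a median of 0.02 that turned to -0.0236 with median centring, and a camera adjusted p of 0.981.

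Many immune and matrix genes rose together (17 of 28 macrophage markers and 26 of 41 matrix genes), with medians of 0.80 for macrophage markers and 0.81 for matrix genes. By itself, a lower share of proximal tubule would raise the other kidney lists alike, and the values argue against it as the sole cause. The highest median among the loop of Henle, collecting duct and podocyte lists was 0.133. The macrophage median exceeded these by 0.814 (95% bootstrap interval 0.477 to 1.13), 0.718 (0.341 to 0.978) and 0.663 (0.296 to 0.915). These intervals, and those of the adipocyte differences below, reflect the spread among the genes of the lists. Such genes are not independent, and the intervals do not measure the spread between mice or RNA pools. A lower share of proximal tubule that came with other changes in cell make-up was not tested and stays open. Fat attached to the kidneys labelled mutant may have contributed, since the adipocyte median was 1.15, with Cfd, Car3, Adipoq and Cidec each above 2.0 on the log2 scale, although 2 of its 12 markers, Lep (-0.14) and Pparg (0.16), named after their values were seen, were not called. The adipocyte median exceeded the macrophage median by 0.349 (-0.109 to 1.41) and the matrix median by 0.336 (-0.0879 to 1.42), intervals that leave this open, and no sample of fat alone was analysed here. An effect of the mutant genotype on immune and stromal cells stays open and was not tested separately from it.

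Of 6 androgen-responsive kidney genes, Slco1a1 (-0.95 ± 0.11, moderated SE, n = 2) and Odc1 (-0.85 ± 0.11) were called lower and 0 higher, as also over the list alone, with a median of -0.19, adjusted p = 0.0015 in camera and adjusted p = 0.335 with an estimated correlation. A different sex make-up of the RNA pools would move Xist and the Y-linked genes apart. The largest absolute log2 ratio of Xist, Ddx3y, Eif2s3y and Kdm5d on either array was 0.327. Their list of 4 held 0 calls on either count, a median of -0.12 and a camera adjusted p of 0.368. As Xist and the Y-linked genes would move in opposite directions, the list median and camera test cannot show a sex difference. Xist had -0.31 and 0.00 on the 2 arrays, which argues against pools of different sex. A genotype effect, and a difference in age or hormone state between pools, stay open and were not tested.

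Of the 24 largest rises and falls 3 lie on the chromosome of Glis2, where 0.78 would be expected from its 3.26% of tested genes: Bfar (55 tested genes away) and Slc49a4 (248 away) fell, and Adipoq (181 away) rose, while Pam16 (-0.89), called lower, is next to Glis2 in the order of tested genes (assembly GRCm38.p6; chosen after its value was seen). A candidate explanation is a strain variant carried along with the altered locus, which could also change how a probe binds, as 1 of 2 Bfar probes gave -2.41 and the other 0.07. Of the 535 tested genes on that chromosome 7.29% were called, against 5.35% of all placed genes; among the 100 tested genes nearest to Glis2, 9 were called, against a median of 5 and a 95th percentile of 10 in windows of that size on other chromosomes, and 158 of 1407 such windows held at least 9. Of the 9, 5 were lower, against a median of 1 per window, and 19 of the 1407 windows, which overlap one another, held at least as many. The count lies between the bounds set for the test, so the explanation stays open, and the strain of the mice is not given in the sources used here.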
